A study of Rattus norvegicus with 9 samples.

How the data were processed

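Messenger RNA of rat striatal tissue was sequenced in 9 libraries, 3 each of the groups Sham, ICH and EDB per the labels. The deposited files hold read counts per gene, 1 library per file, with whole numbers whose totals ran from 14658110 to 17659936. Per the submitters' processing notes the tools were cutadapt, HISAT2, HTSeq and limma on the rat genome build Rnor_6.0. Their versions, roles, annotation release, strand setting and filters are not given in the sources used here. The files pair 22890 gene IDs with counts. Of these IDs, 16799 matched a symbol of a reference gene table made for the assembly GRCr8, which was used for names only, and 3110 carried no symbol. No counts in any library were found for 4803 genes. No positions are given, since the table and the files rest on different assemblies.

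Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr by group, which left 14274, and libraries were scaled by TMM. All 9 libraries entered 1 model with a mean per group, fitted by glmQLFit with robust dispersions, and the 3 pairs of groups were compared by edgeR's quasi-likelihood F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. SE values are those of the fitted log2 fold changes. The 39 gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, two-sided, adjusted over the 38 lists with at least 5 tested members. Lists overlap in members, and they describe transcripts of bulk tissue, not counts of cells. List members that the table lacks or the filter removed were not tested. The groups, comparisons, tests, lists, the alternatives listed below and the rule for naming genes were chosen before the data were examined, and other alternatives were added afterwards.

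By that rule, each comparison names the 8 called genes with the largest rise and the 8 with the largest fall among genes with a symbol, a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries. It also names up to 4 tested members with the smallest p of each list, and 14 genes in every comparison, called or not, of which 13 were in the table. CPM values use the TMM-scaled library sizes. A count of 0 allows up to 3 counts of the total. Intervals are exact Clopper-Pearson intervals at 95% (binom.test), and intervals and floors cover counting error only, since reads from PCR copies are not independent molecules. Sums over libraries were used for genes with few counts. Principal components were computed from log2 CPM of the tested genes.

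Alternatives were RLE scaling, scaling by library size only, no filter on low counts, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, only the 6 libraries compared, the replicate number as a block, an absolute log2 fold change above 1, and leaving out each library in turn. For lists they were also an estimated correlation and fry. Comparisons that share libraries were set beside 50 simulations of unchanged groups, and beside the overlap of independent lists. The procedure was tested on simulated data with 200 changed genes per comparison. Of genes changed 1.5-fold, 2-fold and 4-fold it called 3.13%, 47.0% and 83.3% in ICH against Sham, 12.1%, 50.8% and 84.6% in EDB against ICH and 4.48%, 47.0% and 90.9% in EDB against Sham. It made 2, 5 and 6 false gene calls in these comparisons and 0 false list calls. The simulated genes were drawn independently of each other. The count of false list calls therefore does not cover lists whose genes vary together.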

Results

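RNA sequencing of striatal tissue from rats gave read counts per gene for 9 libraries in 3 groups of 3. The groups were Sham, the control group, ICH, rats with intracerebral hemorrhage (bleeding into the brain tissue), and EDB, named for edaravone dexborneol, a drug that joins the free radical scavenger edaravone with dexborneol. The labels do not state whether the EDB rats also had a hemorrhage, nor the dose, the time or the sex, so EDB was compared with both other groups. Nothing in the labels says that the 3 libraries of a group came from separate animals, so every p-value measures only the spread between these samples. Total counts were 15581052, 15790208 and 14658110 in the Sham libraries, 16927151, 15032157 and 17659936 in the ICH libraries, and 16561053, 16526576 and 16290179 in the EDB libraries. Levels are given as CPM, which are counts scaled by library size, as mean ± SD with n = 3 per group. Changes are given as log2 fold changes ± SE with n = 3 against 3, and a gene is said to have risen or fallen only where its adjusted p was under 0.05. In every gene so described below by name, all 3 libraries of one group lay beyond all 3 of the other.

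Along the first principal component of the log CPM values, which held 41.0% of the variance, the 3 groups separated, with EDB between Sham and ICH. Sham 2 lay apart from Sham 1 and Sham 3 along the second component (19.1%). The share of counts from the 13 mitochondrially encoded genes ran from 2.93% in ICH 2 (95% exact Clopper-Pearson interval 2.92 to 2.94) to 12.03% in Sham 3 (12.02 to 12.05). Albumin transcripts (Alb), made by the liver, stood at 166, 3.21 and 165 CPM in Sham 1, Sham 2 and Sham 3, at 2.27, 21.8 and 18.2 CPM in ICH 1, ICH 2 and ICH 3, and at 2.47, 17.98 and 25.8 CPM in EDB 1, EDB 2 and EDB 3. Of 24 further liver genes with at least 10 counts, written down before their levels were looked at, 17 were highest in Sham 1 and Sham 3. The summed counts of that list showed no excess there, at 1507 and 1409 against 1056 to 1654 in the other 7 libraries, and none of 21 liver genes tested was called in any comparison. Haemoglobin alpha (Hba-a2) stood at 539, 510.4 and 689 CPM in the Sham libraries, 129, 997 and 65.2 CPM in the ICH libraries and 1248, 255 and 1192 CPM in the EDB libraries. Transthyretin (Ttr) and Klotho (Kl), both products of the choroid plexus, stood at 6684 and 204 CPM in EDB 3, against 17.0 to 52.5 and 0.750 to 3.96 CPM in the other 8 libraries. The Y-linked genes Kdm5d and Eif2s3y had no counts in ICH 1, which at 3 counts allows up to 0.175 CPM, and stood at 10.3 to 18.5 and 3.35 to 9.91 CPM elsewhere. Reads shared between close paralogs, such as the haemoglobin and RT1 genes, carry an assignment uncertainty that was not measured.

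**Figure D1:**
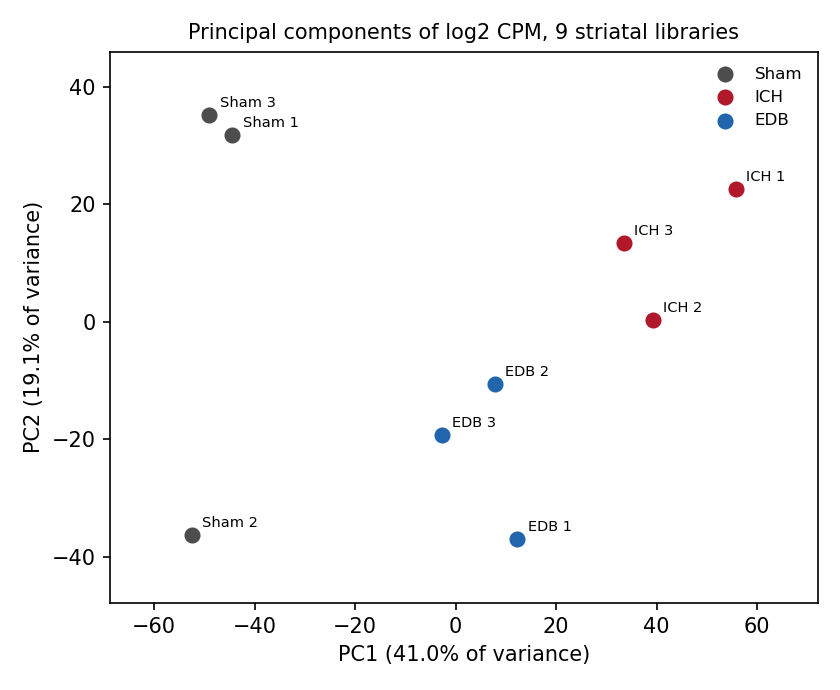
First and second principal components of the log2 CPM values, in arbitrary units, for the 9 libraries coloured by group, with their share of the variance on the axes. The first component (41.0%) separates Sham from ICH with EDB between them, and Sham 2 lies apart from the other Sham libraries on the second (19.1%).

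The ICH and Sham groups were compared to show what intracerebral hemorrhage changed in the striatum. The astrocyte filament Gfap rose from 484 ± 73.2 CPM in Sham to 4918 ± 329 CPM in ICH (log2 fold change 3.34 ± 0.18, adjusted p = 4.67e-06). Haem oxygenase 1 (Hmox1), which breaks down haem, rose from 10.3 ± 1.17 to 448 ± 66.4 CPM (5.45 ± 0.48, adjusted p = 5.86e-05). Spp1, which encodes the secreted protein osteopontin, rose most among the genes named by a rule set in advance (10.69 ± 1.06, adjusted p = 0.000182). Galectin-3 (Lgals3) rose by 6.34 ± 0.53 and the fungal glucan receptor Clec7a by 6.93 ± 0.87, both made by activated phagocytes. The activity-dependent neuronal genes Arc (-2.38 ± 0.35, adjusted p = 0.000960) and Nr4a1 (-2.10 ± 0.27, adjusted p = 0.000353) were lower in ICH.

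Further large rises were those of Slamf9 (6.44 ± 0.63), the imprinted non-coding RNA H19 (6.66 ± 0.77), the hexokinase Hk3 (6.87 ± 1.14), the monocyte-attracting chemokine Ccl2 (6.86 ± 1.02) and Cd8a, a subunit of the CD8 co-receptor (7.63 ± 0.83). Some of these rested on few counts in Sham, so that their fitted changes are not bounds. Hk3 had 3 counts over the Sham libraries against 451 in ICH, a ratio of 130.5 with a 95% counting interval of 44.4 to 635. Ccl2 had 2 counts over the Sham libraries against 311 in ICH, a ratio of 135 with a 95% counting interval of 37.0 to 1119. Cd8a had 3, 1 and 0 counts in Sham 1, Sham 2 and Sham 3, and its ratio was 212 (82.7 to 781). Clec7a had 6 counts over the Sham libraries. The largest falls besides Arc and Nr4a1 were those of the transcription factors Npas4 (-4.48 ± 1.12), Nr4a3 (-2.49 ± 0.48), Egr2 (-2.39 ± 0.53) and Egr4 (-2.33 ± 0.40), the retinol transporter Stra6 (-2.31 ± 0.56) and the melanocortin receptor Mc4r (-2.13 ± 0.56). Npas4 lost its call without Sham 1, Sham 2, ICH 1, ICH 2 or ICH 3 (adjusted p from 0.0535 to 0.0932). Egr2 and Egr4 lost theirs with only the 6 libraries with liver transcripts (adjusted p = 0.111 and 0.0604) and without Sham 2 and ICH 1 (adjusted p = 0.112 and 0.0550), and Egr2 with limma-voom (adjusted p = 0.0527). Stra6 lost it without Sham 1, ICH 1 or ICH 2 (adjusted p from 0.0525 to 0.0574) and Mc4r without Sham 3, ICH 1, ICH 2 or ICH 3 (adjusted p from 0.0513 to 0.0833).

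**Figure D2:**
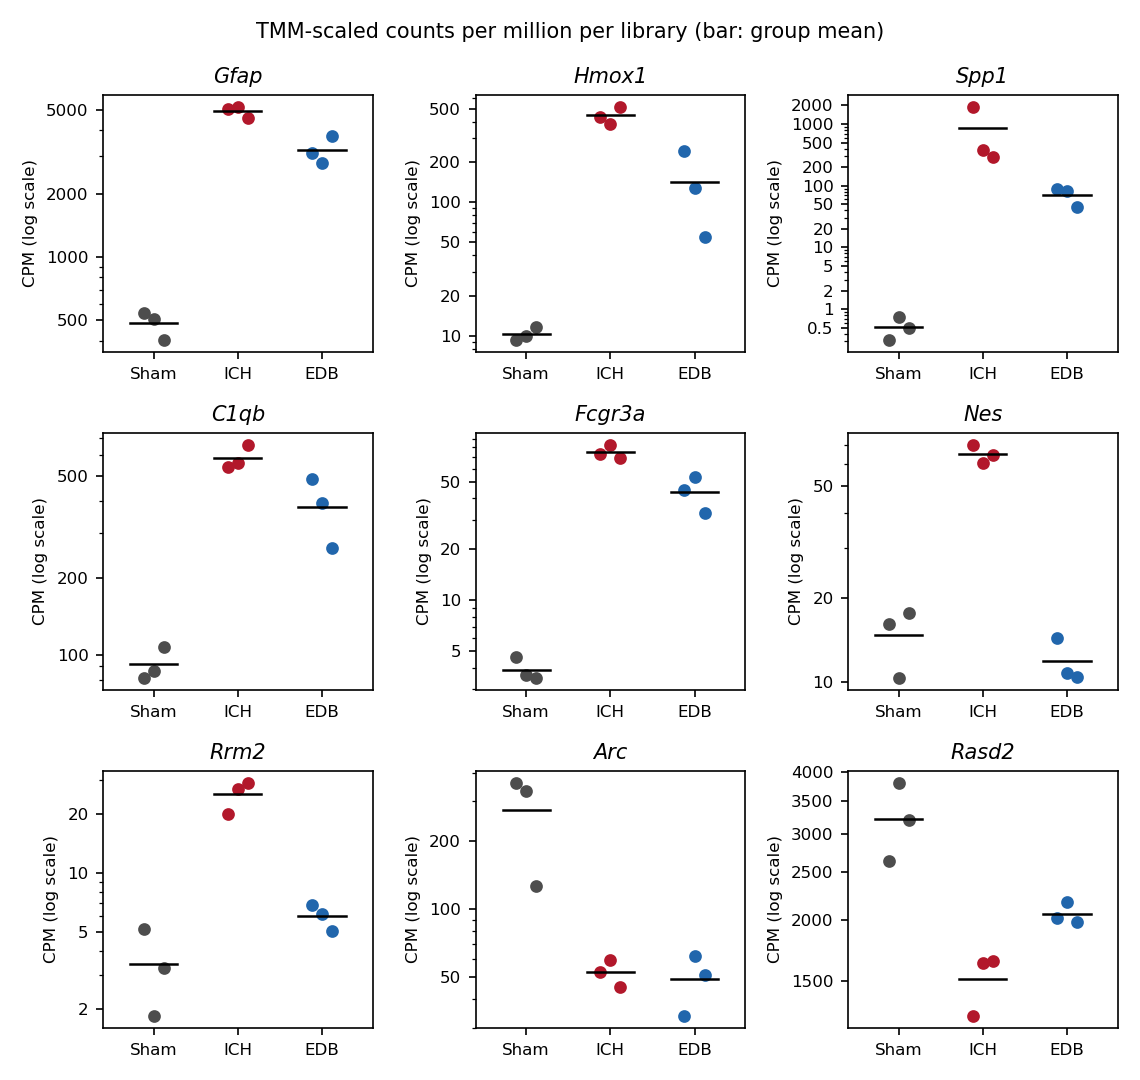
CPM per library on a log axis for Gfap, Hmox1, Spp1, C1qb, Fcgr3a, Nes, Rrm2, Arc and Rasd2 in the 3 libraries of each group, with a bar at the group mean. Gfap, Hmox1, Spp1, C1qb and Fcgr3a lie higher in all ICH libraries than in all Sham libraries, and Nes lies lower in all EDB libraries than in all ICH libraries.

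Of 14 genes chosen in advance, Cldn5 was not analysed here. Besides Gfap and Hmox1, the microglial gene Aif1 rose (2.40 ± 0.24, adjusted p = 7.14e-05), as did the matrix metalloproteinase Mmp9 (2.99 ± 0.75, adjusted p = 0.0177) and Nfe2l2, which encodes the antioxidant regulator Nrf2 (0.96 ± 0.29, adjusted p = 0.0427). The dopamine receptor gene Drd2 fell (-0.57 ± 0.17, adjusted p = 0.0399). Mmp9 lost its call without Sham 3 or ICH 1 (adjusted p from 0.0514 to 0.0646). Nfe2l2 lost it without Sham 1, Sham 2, ICH 1, ICH 3, EDB 1, EDB 2 or EDB 3 (adjusted p from 0.0515 to 0.174), and Drd2 without Sham 2, Sham 3, ICH 1, ICH 2, ICH 3, EDB 1, EDB 2 or EDB 3 (adjusted p from 0.0501 to 0.136), with a log2 fold change of 0.63 for Nfe2l2 without ICH 1 and -0.34 for Drd2 without Sham 2. The others were not called. The cytokine genes Il1b and Tnf had log2 fold changes of 1.39 ± 0.88 and 0.49 ± 0.76 at mean levels under 1 CPM. A rise as large as that of Ccl2 was called from 0.042 CPM in Sham, so only smaller changes of these genes stay open. Aqp4, the astrocyte water channel, had 0.92 ± 0.43, and the antioxidant enzymes Gpx4 and Sod2 had -0.25 ± 0.13 and 0.01 ± 0.11. The dopamine receptor gene Drd1 had -0.23 ± 0.19. Ppp1r1b, which encodes the striatal phosphoprotein DARPP-32, had -0.61 ± 0.23 (adjusted p = 0.0949) and was called as a fall without Sham 3 (adjusted p = 0.0416).

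Gene lists for cell types and processes were fixed in advance, and medians below are medians of the log2 fold change over a list's tested genes. Markers of microglia, macrophages and reactive astrocytes rose together. Of 15 tested microglia and macrophage genes, all 15 rose, with 15 risen adjusted over the list alone (median 2.601, adjusted p = 7.27e-36, held at adjusted p = 0.0338 with an estimated correlation). Examples were Tyrobp, an adaptor of immune receptors (3.29 ± 0.24), and C1qb, a chain of complement C1q (2.68 ± 0.22). Among 13 homeostatic microglia genes, 8 rose and 5 were not called, with 10 risen adjusted over the list alone (median 1.46, adjusted p = 4.69e-12, lost at adjusted p = 0.0707 with an estimated correlation). The growth factor receptor Csf1r rose by 1.97 ± 0.21 and the fractalkine receptor Cx3cr1 by 1.66 ± 0.18. The damage-associated microglia and lysosome list had 19 tested genes, of which 17 rose and 2 were not called, with 17 risen adjusted over the list alone (median 2.34, adjusted p = 3.76e-33, held at adjusted p = 0.0338 with an estimated correlation). They included the glycoprotein Gpnmb (6.01 ± 0.42) and the mitochondrial translocator protein Tspo (3.52 ± 0.25). Among 18 complement and phagocytosis genes, 17 rose and 1 was not called, with 17 risen adjusted over the list alone (median 2.32, adjusted p = 3.70e-37, held at adjusted p = 0.0338 with an estimated correlation). The immunoglobulin receptor Fcgr3a rose by 4.26 ± 0.21, and Serping1, which inhibits C1, by 3.08 ± 0.20. The reactive astrocyte list had 20 tested genes, of which 16 rose and 4 were not called, with 17 risen and 1 fallen adjusted over the list alone (median 1.88, adjusted p = 3.22e-19, held at adjusted p = 0.0338 with an estimated correlation). Beside Gfap, the protease inhibitor Timp1 (4.604 ± 0.37) and the intermediate filament Nes (2.15 ± 0.21) rose.

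Lists named for infiltrating cells and immune signalling rose as well. Of 10 tested monocyte and border macrophage genes, 8 rose and 2 were not called, with 10 risen adjusted over the list alone (median 3.28, adjusted p = 1.95e-10, lost at adjusted p = 0.0583 with an estimated correlation). The lysozyme gene Lyz2 rose by 3.51 ± 0.29, Plac8 by 4.79 ± 0.54 and the calcium-binding S100a4 by 4.62 ± 0.53. Among 7 neutrophil genes, 5 rose and 2 were not called, with 6 risen adjusted over the list alone (median 2.40, adjusted p = 9.91e-05, lost at adjusted p = 0.105 with an estimated correlation). Csf3r, the receptor for granulocyte colony-stimulating factor, rose by 2.79 ± 0.24. The interferon response list had 17 tested genes, of which 13 rose and 4 were not called, with 14 risen adjusted over the list alone (median 1.64, adjusted p = 1.50e-17, lost at adjusted p = 0.0583 with an estimated correlation). The nucleic acid sensor Zbp1 (4.83 ± 0.43) and the antiviral GTPase Mx1 (4.36 ± 0.42) were examples. Of 14 tested antigen presentation genes, 8 rose and 6 were not called, with 11 risen adjusted over the list alone (median 1.91, adjusted p = 4.10e-12, held at adjusted p = 0.0338 with an estimated correlation). The immunoproteasome subunit Psmb8 rose by 1.99 ± 0.16 and the class II gene RT1-DMb by 2.42 ± 0.23. Among 14 cytokine and chemokine genes, 9 rose and 5 were not called, with 9 risen adjusted over the list alone (median 1.91, adjusted p = 3.22e-09, lost at adjusted p = 0.0953 with an estimated correlation). Cxcl16 rose by 2.58 ± 0.18 and the growth factor Tgfb1 by 1.81 ± 0.22. The toll-like receptor and NF-kB list had 20 tested genes, of which 10 rose and 10 were not called, with 10 risen adjusted over the list alone (median 0.80, adjusted p = 9.11e-07, lost at adjusted p = 0.0641 with an estimated correlation). The lipopolysaccharide co-receptor Cd14 (3.78 ± 0.30) and Tlr2 (2.43 ± 0.23) were among them.

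Process lists tied to injury rose in part. Of 14 tested inflammasome and pyroptosis genes, 10 rose and 4 were not called, with 10 risen adjusted over the list alone (median 1.67, adjusted p = 8.31e-07, lost at adjusted p = 0.0928 with an estimated correlation). The sensor Nlrp3 rose by 2.18 ± 0.21 and the pore-forming Gsdmd by 1.54 ± 0.16. Among 9 NADPH oxidase genes, 6 rose and 3 were not called, with 6 risen adjusted over the list alone (median 2.94, adjusted p = 8.09e-10, held at adjusted p = 0.0338 with an estimated correlation). Rac2 (3.29 ± 0.25) and Ncf1 (3.05 ± 0.30), parts of the phagocyte oxidase, rose. The antioxidant list had 22 tested genes, of which 10 rose and 12 were not called, with 11 risen adjusted over the list alone (median 0.35, adjusted p = 5.10e-05, lost at adjusted p = 0.0583 with an estimated correlation). The metal-binding Mt2A (3.07 ± 0.35) and the peroxidase Prdx1 (0.91 ± 0.12) were examples. Of 20 tested iron and haem handling genes, 6 rose and 14 were not called, with 8 risen and 2 fallen adjusted over the list alone (median 0.30, adjusted p = 0.0122, lost at adjusted p = 0.123 with an estimated correlation). Besides Hmox1, the metal transporter Slc11a1 of phagocytes rose by 3.50 ± 0.34. Without Sham 2 (adjusted p = 0.0539) the iron list was no longer called. Among 18 matrix and fibrinolysis genes, 13 rose and 5 were not called, with 14 risen adjusted over the list alone (median 1.92, adjusted p = 3.11e-11, lost at adjusted p = 0.0583 with an estimated correlation). The plasminogen activator Plau rose by 5.11 ± 0.49 and the metalloproteinase Mmp19 by 2.83 ± 0.28.

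Cell division and stress lists moved too. Of 20 tested cell cycle genes, 17 rose and 3 were not called, with 18 risen adjusted over the list alone (median 1.78, adjusted p = 2.34e-12, lost at adjusted p = 0.123 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase (2.88 ± 0.33), and the mitotic gene Birc5 (2.31 ± 0.33) rose. Among 21 apoptosis and p53 genes, 8 rose, 1 fell and 12 were not called, with 9 risen and 1 fallen adjusted over the list alone (median 0.52, adjusted p = 0.00846, lost at adjusted p = 0.123 with an estimated correlation). The pro-apoptotic Bid rose by 1.93 ± 0.22, whereas the initiator caspase gene Casp9 fell (-0.92 ± 0.14). The heat shock list had 16 tested genes, of which 3 rose and 13 were not called, with 3 risen adjusted over the list alone (median 0.12, but 0.02 without Sham 1, 0.30 without Sham 2, 0.20 without Sham 3 and 0.21 without ICH 3, adjusted p = 0.0335, lost at adjusted p = 0.269 with an estimated correlation). Those 3 were the small heat shock protein Hspb1 (3.09 ± 0.29), Sdf2l1 (1.68 ± 0.19) and the co-chaperone Bag3 (0.79 ± 0.15), and the list was not called without Sham 1 (adjusted p = 0.130) or ICH 1 (adjusted p = 0.0724).

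Other lists were lower in ICH. Of 24 tested neuron and synapse genes, 9 fell and 15 were not called, with 11 fallen adjusted over the list alone (median -0.54, but -0.34 without Sham 2, adjusted p = 2.21e-07, lost at adjusted p = 0.104 with an estimated correlation). The postsynaptic scaffolds Shank3 (-1.36 ± 0.14) and Dlg4 (-1.04 ± 0.15) and the kinase Camk2a (-1.05 ± 0.18) fell. Among 24 striatal projection neuron genes, 12 fell and 12 were not called, with 14 fallen adjusted over the list alone (median -0.58, but -0.36 without Sham 2, adjusted p = 5.10e-07, lost at adjusted p = 0.269 with an estimated correlation). The striatal GTPase Rasd2 fell by 1.08 ± 0.17 and the adenosine receptor Adora2a by 0.81 ± 0.18. The striatal interneuron list had 10 tested genes, of which 3 fell and 7 were not called, with 3 fallen adjusted over the list alone (median -0.49, adjusted p = 0.0314, lost at adjusted p = 0.269 with an estimated correlation). They were Lhx6 (-0.76 ± 0.16), Nos1 (-0.90 ± 0.25) and Nkx2-1 (-0.82 ± 0.26), of which Nos1 lost its call without Sham 2, Sham 3, ICH 1 or ICH 3 (adjusted p from 0.0604 to 0.0933) and Nkx2-1 without Sham 1, Sham 2, Sham 3, ICH 1, ICH 2, ICH 3, EDB 1 or EDB 2 (adjusted p from 0.0539 to 0.129). The interneuron list itself was not called without Sham 2 (adjusted p = 0.0570) or Sham 3 (adjusted p = 0.0502). Of 14 tested immediate early genes, 1 rose, 9 fell and 4 were not called, with 1 risen and 10 fallen adjusted over the list alone (median -1.45, adjusted p = 1.18e-06, held at adjusted p = 0.0482 with an estimated correlation). Egr1 fell by 1.28 ± 0.23, beside Arc and Nr4a1.

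Among 14 endothelial and barrier genes, 2 fell and 12 were not called, with 2 fallen adjusted over the list alone (median -0.41, adjusted p = 0.0121, lost at adjusted p = 0.347 with an estimated correlation). Those were the tight junction gene Lsr (-0.89 ± 0.16) and the growth factor receptor Flt1 (-0.77 ± 0.18, or -0.49 without Sham 3), and the list was not called without Sham 3 (adjusted p = 0.0660). The respiratory chain list had 18 tested genes, of which 3 fell and 15 were not called, with 3 fallen adjusted over the list alone (median -0.21, but -0.09 without Sham 2, adjusted p = 0.0329, lost at adjusted p = 0.565 with an estimated correlation). Cox6a1 (-0.61 ± 0.12), Ndufb8 (-0.53 ± 0.15) and Cox4i1 (-0.51 ± 0.15) were the ones. Ndufb8 lost its call without Sham 2, ICH 1, ICH 2 or ICH 3 (adjusted p from 0.0536 to 0.105) and Cox4i1 without Sham 2, ICH 1, ICH 2, ICH 3 or EDB 1 (adjusted p from 0.0541 to 0.132). The respiratory chain list was not called without Sham 2 (adjusted p = 0.246) or ICH 1 (adjusted p = 0.0731), nor with scaling by library size alone (adjusted p = 0.0709). Of 15 tested cholesterol synthesis genes, 2 fell and 13 were not called, with 1 fallen adjusted over the list alone (median -0.37, but -0.64 without ICH 2, adjusted p = 0.00817, lost at adjusted p = 0.520 with an estimated correlation). They were Msmo1 (-0.79 ± 0.20) and Insig1 (-0.68 ± 0.21), of which Msmo1 lost its call without ICH 3 (adjusted p = 0.0732) and Insig1 without Sham 1, Sham 2, Sham 3, ICH 1, ICH 2, ICH 3, EDB 1 or EDB 2 (adjusted p from 0.0504 to 0.125). The cholesterol list was not called without ICH 3 (adjusted p = 0.0842). Among 12 oligodendrocyte precursor genes, 7 rose and 5 were not called, with 10 risen adjusted over the list alone (median 0.64, adjusted p = 0.000142, lost at adjusted p = 0.105 with an estimated correlation). Gpr17 (1.01 ± 0.16) and Bcas1 (0.85 ± 0.16), both of early oligodendrocytes, rose.

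The other lists were not called by camera, while fry called 2 of them upward, ferroptosis (adjusted p = 0.00937) and hypoxia (adjusted p = 0.0387). Of the lists called by camera, fry did not call respiratory chain (adjusted p = 0.112) and cholesterol synthesis (adjusted p = 0.133). Oligodendrocyte genes had a median of 0.42 (adjusted p = 0.161), with Aspa risen (1.07 ± 0.18) as the single call among 15, and the list was called upward without Sham 2 (adjusted p = 0.0156) or ICH 3 (adjusted p = 0.000839). Astrocyte baseline genes had a median of -0.13 (adjusted p = 0.533), with 3 risen, among them the gap junction gene Gja1 (0.60 ± 0.14), and 3 fallen. Pericyte genes had a median of -0.27 (adjusted p = 0.136), with 4 fallen, among them Vtn (-0.97 ± 0.14) and Notch3 (-0.80 ± 0.16), and Anpep (2.06 ± 0.38) and Tagln (2.33 ± 0.50) risen. Tagln lost its call without Sham 2 or Sham 3 (adjusted p from 0.0511 to 0.0516), and the pericyte list was called downward without Sham 1 (adjusted p = 0.0371). Fibroblast genes had a median of 0.76 (adjusted p = 0.161), with Postn (5.07 ± 1.31), Col6a3 (2.48 ± 0.68) and Fbln1 (0.59 ± 0.18) risen, and were called without ICH 2 (adjusted p = 0.0449). The change of Postn was 2.67 without ICH 1 and 9.22 without Sham 1. Postn lost its call without Sham 2, Sham 3 or ICH 1 (adjusted p from 0.0738 to 0.130), Col6a3 without Sham 1, Sham 2, Sham 3, ICH 1 or ICH 2 (adjusted p from 0.0523 to 0.102) and Fbln1 without Sham 1, Sham 2, Sham 3, ICH 1, ICH 2 or ICH 3 (adjusted p from 0.0514 to 0.131). Ferroptosis genes had a median of 0.40 (adjusted p = 0.0630), with 5 risen, Hmox1 and the polyamine enzyme Sat1 (0.80 ± 0.17) among them, and were called without Sham 3 (adjusted p = 0.0435). Hypoxia genes had a median of 0.26 (adjusted p = 0.518), with 3 risen, among them adrenomedullin (Adm, 2.54 ± 0.37), and 2 fallen.

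Erythroid genes had a median of -0.20 and a mean of 0.18, and the test pointed down (adjusted p = 0.921). They were called downward with a median of -2.05 without ICH 2 (adjusted p = 0.0482), the library with the highest Hba-a2 level in that group. Thalamic and pallidal genes had a median of 0.06 and a mean of -0.04 with the test pointing up (adjusted p = 0.921), with Prkcd risen (1.29 ± 0.17) and Gbx2 fallen (-1.67 ± 0.38). Ependymal and choroid plexus genes had a median of 0.09 with the test pointing down (adjusted p = 0.921). Cortical excitatory neuron genes had a median of -0.17 (adjusted p = 0.592). GABA-A receptor genes had a median of -0.13 (adjusted p = 0.203), and were called downward with only the 6 libraries with liver transcripts (median -0.44) and without Sham 2 and ICH 1 (median -0.44), with Gabrd fallen (-0.67 ± 0.20), a call lost without Sham 2, ICH 1, ICH 2, ICH 3 or EDB 3 (adjusted p from 0.0501 to 0.122), with a log2 fold change of -0.38 without Sham 2. Of the lymphocyte markers only 4 were tested, too few for a list test. Cd8a rose, and the T cell genes Lck, Cd3e and Cd5 had 0.57 ± 0.35, -0.58 ± 0.68 and 0.63 ± 0.98.

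In edgeR's quasi-likelihood test, 2670 of 14274 genes passed the Benjamini-Hochberg adjusted threshold of 0.05, 1628 of them higher in ICH and 1042 lower. At an unadjusted p under 0.05 there were 4501. Of the called genes, 1189 changed more than 2-fold, 976 up and 213 down. The 3 ICH and 3 Sham libraries did not overlap in 35.6% of genes, where chance gives 10%. Scaling by library size alone called 2699 genes and moved the share of rises from 61.0% to 74.4%, since the median log2 fold change of all genes was then 0.10. The share ran from 48.4% with Sham 2 as the only Sham library, where falls outnumbered rises, to 82.1% with an absolute log2 fold change above 1. Leaving out ICH 1 called 1769 genes. Of the 38 lists tested, 27 were called with camera's preset correlation, 20 up and 7 down, and 7 with an estimated correlation, 6 up and 1 down. In 1 or more of the fits added after the data were seen, camera did not call the striatal interneuron, iron, apoptosis, respiratory chain, heat shock and endothelial lists (adjusted p from 0.0630 to 0.499) and called the GABA-A receptor list, and with only the 6 libraries with liver transcripts 18 of the 92 named calls were lost.

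The EDB and ICH groups were compared to show how striatal expression differed in rats given the drug. The intermediate filament Nes, found in reactive astrocytes, fell from 65.0 ± 4.95 CPM in ICH to 11.9 ± 2.20 CPM in EDB (log2 fold change -2.45 ± 0.21, adjusted p = 0.00242). It was the only gene named for this comparison that kept its call without each of the 9 libraries in turn. The hyaluronan receptor Cd44 fell by 1.62 ± 0.22 (adjusted p = 0.0197) and S100a10, a partner of annexin A2, by 1.98 ± 0.26 (adjusted p = 0.0197). Cd44 lost its call without EDB 2 (adjusted p = 0.0586) and S100a10 without ICH 2 or EDB 3 (adjusted p from 0.0536 to 0.0640). Gpnmb and Lgals3, both high in phagocytes, fell by 2.58 ± 0.35 and 2.44 ± 0.42. Gpnmb lost its call without ICH 2, EDB 2 or EDB 3 (adjusted p from 0.0511 to 0.0745) and Lgals3 without Sham 1, Sham 3, ICH 1, ICH 2, ICH 3, EDB 2 or EDB 3 (adjusted p from 0.0634 to 0.0917).

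Further large falls were those of H19 (-4.11 ± 0.62), Cd300le (-3.52 ± 0.59), Cd8a (-3.26 ± 0.57), the membrane metalloproteinase Adam8 (-3.23 ± 0.49) and the interferon-induced Ifitm1 (-2.79 ± 0.52). The rises were smaller. The metalloreductase Steap2 had 1.03 ± 0.20, the dicarboxylate transporter Slc13a3 0.97 ± 0.18 and the calmodulin regulator Pcp4 0.96 ± 0.17. Prodh1, which encodes proline dehydrogenase, rose by 0.81 ± 0.14, Rell2 by 0.73 ± 0.14, Mcf2l by 0.63 ± 0.11 and Tcte1 by 0.58 ± 0.11. Each of these 7 rises lost its call without 1 or more libraries other than Sham 2 (adjusted p from 0.0514 to 0.198). Of the falls, H19 lost its call without ICH 1, ICH 2, ICH 3, EDB 2 or EDB 3 (adjusted p from 0.0632 to 0.0880), Cd300le without Sham 1, Sham 3, ICH 1, ICH 2, EDB 2 or EDB 3 (adjusted p from 0.0631 to 0.0942) and Cd8a without Sham 1, Sham 3, ICH 1, ICH 2, EDB 1, EDB 2 or EDB 3 (adjusted p from 0.0571 to 0.107). Adam8 lost it without ICH 1, ICH 2, EDB 2 or EDB 3 (adjusted p from 0.0594 to 0.0880) and Ifitm1 without Sham 1, Sham 3, ICH 1, ICH 2, EDB 1, EDB 2 or EDB 3 (adjusted p from 0.0677 to 0.116), with a log2 fold change of -1.86 without ICH 1.

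None of the 13 genes chosen in advance was called. Hmox1 had -1.67 ± 0.40 (adjusted p = 0.0920) with 141 ± 93.1 CPM in EDB, and was called as a fall without EDB 1 (adjusted p = 0.0221). Gfap had -0.60 ± 0.16 (adjusted p = 0.109) with 3234 ± 491 CPM in EDB. Aif1 had -0.67 ± 0.22, Mmp9 -1.79 ± 0.69, Aqp4 -1.14 ± 0.43 and Nfe2l2 -0.76 ± 0.29. The antioxidant genes Gpx4 and Sod2 had 0.20 ± 0.13 and 0.21 ± 0.11. Among striatal neuron genes, Drd1 had 0.28 ± 0.19, Drd2 0.28 ± 0.17 and Ppp1r1b 0.43 ± 0.23. Il1b and Tnf, under 1 CPM in both groups, had -0.55 ± 0.81 and -0.40 ± 0.75.

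Most called lists were lower in EDB than in ICH, with few single genes called. Of 19 tested damage-associated microglia and lysosome genes, 5 fell and 14 were not called, with 15 fallen adjusted over the list alone (median -1.06, adjusted p = 3.19e-20, lost at adjusted p = 0.0919 with an estimated correlation). The lipid droplet protein Plin2 (-1.63 ± 0.26) and the protease Ctsb (-0.93 ± 0.16) fell beside Gpnmb and Lgals3. The reactive astrocyte list had 20 tested genes, of which 6 fell and 14 were not called, with 12 fallen adjusted over the list alone (median -1.33, but -0.83 without ICH 1, adjusted p = 1.26e-19, lost at adjusted p = 0.0919 with an estimated correlation). Beside Nes, Cd44 and S100a10, the small heat shock protein Hspb1 fell by 1.85 ± 0.27. Among 20 cell cycle genes, 3 fell and 17 were not called, with 19 fallen adjusted over the list alone (median -1.49, adjusted p = 3.19e-20, lost at adjusted p = 0.158 with an estimated correlation). They were Rrm2 (-2.07 ± 0.31), the replication helicase subunit Mcm3 (-1.34 ± 0.25) and the mitotic kinase Plk1 (-1.66 ± 0.32). None of the 15 microglia and macrophage genes was called, with 13 fallen adjusted over the list alone (median -0.77, adjusted p = 2.94e-10, lost at adjusted p = 0.215 with an estimated correlation). Tyrobp, at adjusted p = 0.121, had -0.77 ± 0.22. The complement and phagocytosis list had 18 tested genes, of which 1 fell and 17 were not called, with 14 fallen adjusted over the list alone (median -0.65, adjusted p = 3.90e-10, lost at adjusted p = 0.158 with an estimated correlation). That gene was Serping1 (-1.09 ± 0.19), while Fcgr3a had -0.78 ± 0.18. Apart from Nes, each of the genes called here lost its call without 1 or more of Sham 1, Sham 3, ICH 1, ICH 2, ICH 3, EDB 1, EDB 2 and EDB 3 (adjusted p from 0.0511 to 0.173).

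Of 18 tested matrix and fibrinolysis genes, 3 fell and 15 were not called, with 13 fallen adjusted over the list alone (median -1.18, adjusted p = 1.43e-10, lost at adjusted p = 0.134 with an estimated correlation). Plau (-2.31 ± 0.40), Timp1 (-1.604 ± 0.31) and the matrix protein Tgfbi (-1.37 ± 0.27) were the ones. Among 10 monocyte and border macrophage genes, 2 fell and 8 were not called, with 6 fallen adjusted over the list alone (median -1.496, adjusted p = 6.09e-08, lost at adjusted p = 0.158 with an estimated correlation). They were Lyz2 (-1.84 ± 0.27) and the arginase Arg1 (-1.88 ± 0.35). The toll-like receptor and NF-kB list had 20 tested genes, of which 1 fell and 19 were not called, with 6 fallen adjusted over the list alone (median -0.63, but -0.41 without ICH 1, adjusted p = 1.91e-06, lost at adjusted p = 0.144 with an estimated correlation). That was Cd14 (-1.34 ± 0.26). Of 9 tested NADPH oxidase genes, 1 fell and 8 were not called, with 6 fallen adjusted over the list alone (median -0.74, adjusted p = 3.85e-06, lost at adjusted p = 0.134 with an estimated correlation). Cyba, a membrane subunit of the oxidase, was that gene (-1.14 ± 0.22). Among 14 cytokine and chemokine genes, 1 fell and 13 were not called, with 5 fallen adjusted over the list alone (median -0.72, adjusted p = 4.42e-05, lost at adjusted p = 0.220 with an estimated correlation). It was Cxcl16 (-0.94 ± 0.17). The immediate early list had 14 tested genes, of which 1 fell and 13 were not called, with 2 fallen adjusted over the list alone (median -0.34, adjusted p = 0.0147, lost at adjusted p = 0.215 with an estimated correlation). Fos was the gene (-1.67 ± 0.32), and the list was not called without EDB 1 (adjusted p = 0.0524). Each of these genes lost its call without 1 or more libraries other than Sham 2 (adjusted p from 0.0522 to 0.196).

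Several lists were lower in EDB without any single gene called. None of the 17 interferon response genes was called, with 1 fallen adjusted over the list alone (median -0.44, but -0.82 without EDB 2, adjusted p = 2.21e-05, lost at adjusted p = 0.252 with an estimated correlation). No single gene of the 7 on the neutrophil list was called, with 3 fallen adjusted over the list alone (median -0.96, but -1.52 without EDB 1, adjusted p = 0.000960, lost at adjusted p = 0.215 with an estimated correlation). In the antigen presentation list none of 14 genes was called, with 4 fallen adjusted over the list alone (median -0.48, but -0.27 without ICH 1, adjusted p = 0.00281, lost at adjusted p = 0.215 with an estimated correlation). None of the 14 inflammasome and pyroptosis genes was called, nor was any adjusted over the list alone (median -0.60, but -0.32 without ICH 1, adjusted p = 0.00361, lost at adjusted p = 0.290 with an estimated correlation). Both of the last were not called without ICH 1 (adjusted p = 0.0683 and 0.0817). No single gene of the 22 on the antioxidant list was called, with 4 fallen adjusted over the list alone (median -0.20, adjusted p = 0.00754, lost at adjusted p = 0.215 with an estimated correlation). The antioxidant list was not called without EDB 2 (adjusted p = 0.0800). In the homeostatic microglia list none of 13 genes was called, with 1 fallen adjusted over the list alone (median -0.44, but -0.23 without EDB 3, adjusted p = 0.00754, lost at adjusted p = 0.408 with an estimated correlation). It was not called without EDB 3 (adjusted p = 0.171). No single gene of the 21 on the apoptosis and p53 list was called, with 7 fallen adjusted over the list alone (median -0.43, adjusted p = 0.0132, lost at adjusted p = 0.215 with an estimated correlation). That list was not called without ICH 1 (adjusted p = 0.0579).

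No single gene of the 17 on the ferroptosis list was called, with 3 fallen adjusted over the list alone (median -0.27, but -0.13 without EDB 2, adjusted p = 0.0285, lost at adjusted p = 0.290 with an estimated correlation). The ferroptosis list was not called without ICH 1 (adjusted p = 0.0676) or EDB 2 (adjusted p = 0.188). None of the 12 oligodendrocyte precursor genes was called, with 4 fallen adjusted over the list alone (median -0.20, adjusted p = 0.0376, lost at adjusted p = 0.326 with an estimated correlation). Leaving out ICH 1 (adjusted p = 0.0944), ICH 2 (adjusted p = 0.169), EDB 1 (adjusted p = 0.117) or EDB 3 (adjusted p = 0.106) ended that call, as did a replicate block (adjusted p = 0.0502). Other lists were higher in EDB, with no single gene of theirs called in the fit of all 9 libraries. In the respiratory chain list none of 18 genes was called, nor was any adjusted over the list alone (median 0.29, adjusted p = 2.70e-06, lost at adjusted p = 0.232 with an estimated correlation). Cox6a1 had 0.40 ± 0.12. None of the 24 striatal projection neuron genes was called, nor was any adjusted over the list alone (median 0.30, adjusted p = 4.73e-06, lost at adjusted p = 0.323 with an estimated correlation). The opioid precursor Penk had 0.59 ± 0.16. No single gene of the 15 on the oligodendrocyte list was called, nor was any adjusted over the list alone (median 0.45, but 0.76 without ICH 1 and 0.26 without ICH 3, adjusted p = 2.08e-05, lost at adjusted p = 0.322 with an estimated correlation). Mbp, the myelin basic protein, had 0.80 ± 0.27. In the neuron and synapse list none of 24 genes was called, with 4 risen adjusted over the list alone (median 0.20, but 0.31 without ICH 3, adjusted p = 2.21e-05, lost at adjusted p = 0.215 with an estimated correlation). The synaptic vesicle protein Syp had 0.81 ± 0.19 and the neurofilament Nefh 1.21 ± 0.28. Without Sham 2, Syp, Nefh and Penk were called as rises (adjusted p = 0.0272, 0.0425 and 0.0329).

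No single gene of the 15 on the cholesterol synthesis list was called, nor was any adjusted over the list alone (median 0.17, but 0.29 without ICH 1, -0.03 without ICH 3, 0.30 without EDB 1, 0.11 without EDB 2 and -0.07 without EDB 3, adjusted p = 0.0178, lost at adjusted p = 0.551 with an estimated correlation). It was not called without ICH 3 (adjusted p = 0.486) or EDB 3 (adjusted p = 0.390). None of the 12 ependymal and choroid plexus genes was called, nor was any adjusted over the list alone (median 3.02, but 0.07 without EDB 3, adjusted p = 0.0280, lost at adjusted p = 0.593 with an estimated correlation). Ttr and Kl were high in EDB 3 alone. Without ICH 1 (adjusted p = 0.0676), ICH 2 (adjusted p = 0.1498) or EDB 3 (adjusted p = 0.322) the choroid plexus list was not called. The remaining lists were not called by camera. Erythroid genes had a median of 1.11 (adjusted p = 0.242) and were called upward without ICH 2 (adjusted p = 2.85e-05) or EDB 2 (adjusted p = 0.0192), with medians of 2.97 and 1.58. Among the ICH libraries, Hba-a2 was highest in ICH 2. Iron genes had a median of -0.23 (adjusted p = 0.227) and were called downward without EDB 1 (adjusted p = 0.00714). Striatal interneuron genes had a median of 0.25 (adjusted p = 0.140) and were called upward without EDB 3 (adjusted p = 0.0222). Pericyte genes had a median of -0.21 (adjusted p = 0.0532), with the aminopeptidase Anpep fallen (-2.13 ± 0.38), and were called without ICH 3 (adjusted p = 0.0159), EDB 1 (adjusted p = 0.00156) or EDB 3 (adjusted p = 0.0477), or with scaling by library size alone (adjusted p = 0.0477). Anpep lost its call without Sham 1, Sham 3, ICH 1, ICH 2, EDB 1, EDB 2 or EDB 3 (adjusted p from 0.0598 to 0.115).

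Fibroblast genes had a median of -0.30 (adjusted p = 0.256) and were called downward without EDB 1 (adjusted p = 0.00434). Heat shock genes had a median of -0.09 (adjusted p = 0.183), with Hspb1 alone fallen, and hypoxia genes had a median of -0.01 (adjusted p = 0.595), with the vessel factor Angpt2 fallen (-1.74 ± 0.34). Each of the pair lost its call without 1 or more libraries other than Sham 2 (adjusted p from 0.0568 to 0.193). Astrocyte baseline genes had a median of -0.09 (adjusted p = 0.513), endothelial genes a median of -0.04 (adjusted p = 0.803) and cortical neuron genes a median of -0.47 (adjusted p = 0.803). Thalamic genes had a median of -0.19 but a mean of 0.01, with the test pointing down (adjusted p = 0.954). GABA-A receptor genes had a median of -0.19 and a mean of -0.06, while the test pointed up (adjusted p = 0.813). Among the 4 lymphocyte markers, Cd8a fell, and Cd3e, Cd5 and Lck had 0.61 ± 0.67, -0.54 ± 0.96 and -0.17 ± 0.35. As given above, Cd8a lost its call without some single libraries.

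The quasi-likelihood test called 98 of 14274 genes, 8 higher in EDB and 90 lower, of which 67 changed more than 2-fold. At an unadjusted p under 0.05 there were 2318, and the libraries of the groups did not overlap in 25.2% of genes, where chance gives 10%. The count moved with single libraries, to 24, 8 and 32 without ICH 1, ICH 2 and ICH 3, and to 44, 9 and 10 without EDB 1, EDB 2 and EDB 3. It moved with the Sham libraries too, which enter the model but not this contrast, to 41, 321 and 37 without Sham 1, Sham 2 and Sham 3. With a replicate block it was 58, and with DESeq2 679. The few rises depended on the fit, with 0 rises with the block, 92 without Sham 2 and 204 with DESeq2. Of the 35 called genes named for this comparison, leaving out ICH 1, ICH 2 or ICH 3 ended the calls of 29, 33 and 21, EDB 1, EDB 2 or EDB 3 of 20, 32 and 32, and Sham 1 or Sham 3 of 22 and 25, at adjusted p from 0.0511 to 0.198. Camera called 26 of 38 lists with the preset correlation, 6 up and 20 down, and none with an estimated correlation. Fry, which tests whether a list's genes move one way on balance, called 11, all down. In 1 or more of the fits added after the data were seen, camera did not call the homeostatic microglia, oligodendrocyte precursor, inflammasome, apoptosis, antigen presentation, immediate early, choroid plexus and ferroptosis lists (adjusted p from 0.0535 to 0.128) and called the pericyte and fibroblast lists, and with only the 6 libraries with liver transcripts 23 of the 35 named calls were lost.

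The EDB and Sham groups were compared to show how the EDB group differed from the control striatum. Gfap was 3234 ± 491 CPM in EDB and 484 ± 73.2 CPM in Sham (log2 fold change 2.74 ± 0.17, adjusted p = 4.76e-05). Hmox1 rose by 3.78 ± 0.45 (adjusted p = 0.00113) and Spp1 by 7.10 ± 0.998 (adjusted p = 0.00340). The Fc receptor-like gene Fcrl2 (4.87 ± 0.37), the sensor Zbp1 (4.28 ± 0.43), Lgals3 (3.90 ± 0.51), Plac8 (4.30 ± 0.54) and S100a4 (3.52 ± 0.52) rose too. The phospholipase Pla2g5 rose by 4.53 ± 1.11, a call lost without Sham 1, Sham 2, Sham 3, ICH 2 or EDB 3 (adjusted p from 0.0556 to 0.154), with a log2 fold change of 2.30 without EDB 3.

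The falls were led by immediate early genes of neuronal activity, Egr2 (-3.16 ± 0.55), Nr4a3 (-2.56 ± 0.48), Arc (-2.48 ± 0.36), Nr4a1 (-2.34 ± 0.27), Fos (-2.30 ± 0.32), Fosb (-2.12 ± 0.32) and Fosl2 (-2.03 ± 0.26). The endothelial early response gene Apold1 fell by 2.22 ± 0.47, a call lost without Sham 2 or Sham 3 (adjusted p from 0.0506 to 0.0667). Of the genes chosen in advance, Aif1 rose (1.73 ± 0.23, adjusted p = 0.00166) beside Gfap and Hmox1. The others were not called. Nfe2l2 had 0.20 ± 0.29, Mmp9 1.21 ± 0.77, Aqp4 -0.22 ± 0.43, Gpx4 -0.05 ± 0.13 and Sod2 0.22 ± 0.11. Drd1 had 0.05 ± 0.19, Drd2 -0.30 ± 0.17 and Ppp1r1b -0.18 ± 0.23. Il1b and Tnf, under 1 CPM, had 0.85 ± 0.91 and 0.09 ± 0.77.

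Microglial, macrophage and complement lists were above Sham. Of 18 tested complement and phagocytosis genes, 15 rose and 3 were not called, with 16 risen adjusted over the list alone (median 1.87, adjusted p = 1.75e-36, held at adjusted p = 0.0376 with an estimated correlation). Fcgr3a (3.48 ± 0.21) and the protease C1r (1.27 ± 0.12) were examples. Among 15 microglia and macrophage genes, 13 rose and 2 were not called, with 15 risen adjusted over the list alone (median 1.90, adjusted p = 1.38e-34, lost at adjusted p = 0.0503 with an estimated correlation). Tyrobp rose by 2.52 ± 0.24 and C1qb by 2.05 ± 0.21. The damage-associated microglia and lysosome list had 19 tested genes, of which 14 rose and 5 were not called, with 15 risen adjusted over the list alone (median 1.24, adjusted p = 9.37e-24, held at adjusted p = 0.0376 with an estimated correlation). The lysosomal protease Ctsz (2.27 ± 0.23) and Tspo (2.33 ± 0.24) were among them. Of 13 tested homeostatic microglia genes, 7 rose and 6 were not called, with 8 risen adjusted over the list alone (median 0.79, adjusted p = 4.17e-13, lost at adjusted p = 0.101 with an estimated correlation). Csf1r rose by 1.55 ± 0.21 and Cx3cr1 by 1.22 ± 0.17. Among 17 interferon response genes, 13 rose and 4 were not called, with 13 risen adjusted over the list alone (median 1.203, adjusted p = 2.75e-16, lost at adjusted p = 0.0789 with an estimated correlation). Mx1 rose by 3.47 ± 0.40, beside Zbp1. The antigen presentation list had 14 tested genes, of which 7 rose and 7 were not called, with 10 risen adjusted over the list alone (median 1.40, adjusted p = 3.41e-12, held at adjusted p = 0.0376 with an estimated correlation). Psmb8 (1.496 ± 0.16) and RT1-DMb (1.70 ± 0.23) rose.

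Among 20 reactive astrocyte genes, 6 rose and 14 were not called, with 9 risen adjusted over the list alone (median 0.69, adjusted p = 4.35e-07, lost at adjusted p = 0.151 with an estimated correlation). Timp1 (3.0 ± 0.36) and the transcription factor Stat3 (0.66 ± 0.12) rose beside Gfap. Of 9 tested NADPH oxidase genes, 5 rose and 4 were not called, with 6 risen and 1 fallen adjusted over the list alone (median 1.52, adjusted p = 8.90e-07, lost at adjusted p = 0.0604 with an estimated correlation). Rac2 rose by 2.55 ± 0.24 and Ncf1 by 2.32 ± 0.30. The cytokine and chemokine list had 14 tested genes, of which 5 rose and 9 were not called, with 9 risen adjusted over the list alone (median 1.28, adjusted p = 5.68e-07, lost at adjusted p = 0.151 with an estimated correlation). Cxcl16 (1.64 ± 0.18) and the growth factor Csf1 (1.22 ± 0.19) were examples. Among 10 monocyte and border macrophage genes, 4 rose and 6 were not called, with 6 risen adjusted over the list alone (median 1.93, adjusted p = 3.95e-06, lost at adjusted p = 0.151 with an estimated correlation). Lyz2 rose by 1.68 ± 0.27, beside Plac8 and S100a4. Of 7 tested neutrophil genes, 1 rose and 6 were not called, with 2 risen adjusted over the list alone (median 1.19, but 0.73 without EDB 1, adjusted p = 0.00480, lost at adjusted p = 0.228 with an estimated correlation). That gene was Csf3r (1.92 ± 0.24). The toll-like receptor and NF-kB list had 20 tested genes, of which 4 rose and 16 were not called, with 7 risen and 1 fallen adjusted over the list alone (median 0.37, adjusted p = 0.00593, lost at adjusted p = 0.228 with an estimated correlation). Cd14 rose by 2.43 ± 0.30 and Tlr2 by 1.605 ± 0.23.

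Of 18 tested matrix and fibrinolysis genes, 5 rose and 13 were not called, with 6 risen adjusted over the list alone (median 0.76, adjusted p = 3.95e-05, lost at adjusted p = 0.165 with an estimated correlation). Mmp19 rose by 1.85 ± 0.28. Among 14 inflammasome and pyroptosis genes, 5 rose and 9 were not called, with 8 risen adjusted over the list alone (median 0.95, adjusted p = 2.64e-05, lost at adjusted p = 0.153 with an estimated correlation). Nlrp3 (1.62 ± 0.21) and Gsdmd (1.23 ± 0.16) rose. The antioxidant list had 22 tested genes, of which 6 rose, 1 fell and 15 were not called, with 6 risen and 1 fallen adjusted over the list alone (median 0.21, adjusted p = 0.000837, lost at adjusted p = 0.116 with an estimated correlation). Mt2A rose by 2.01 ± 0.34 and Prdx1 by 0.76 ± 0.12. Of 20 tested iron and haem handling genes, 4 rose and 16 were not called, with 7 risen and 3 fallen adjusted over the list alone (median 0.24, adjusted p = 0.0105, lost at adjusted p = 0.165 with an estimated correlation). Slc11a1 rose by 2.55 ± 0.33, and the list was not called without Sham 2 (adjusted p = 0.134). Among 15 oligodendrocyte genes, 3 rose and 12 were not called, with 12 risen adjusted over the list alone (median 0.84, adjusted p = 2.00e-07, lost at adjusted p = 0.228 with an estimated correlation). They were Aspa (1.01 ± 0.18), the regulator Myrf (0.99 ± 0.25) and the tight junction gene Cldn11 (1.23 ± 0.31). Myrf lost its call without Sham 1, Sham 3, ICH 2, EDB 1, EDB 2 or EDB 3 (adjusted p from 0.0537 to 0.122) and Cldn11 without Sham 1, Sham 3, ICH 2, EDB 1, EDB 2 or EDB 3 (adjusted p from 0.0559 to 0.125). The oligodendrocyte precursor list had 12 tested genes, of which 4 rose and 8 were not called, with 4 risen adjusted over the list alone (median 0.36, adjusted p = 0.00110, lost at adjusted p = 0.165 with an estimated correlation). Olig1 was one of them (0.78 ± 0.16), a call lost without Sham 1, Sham 3 or EDB 1 (adjusted p from 0.0514 to 0.0723).

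Cell cycle genes were higher as a list without any gene called. None of the 20 cell cycle genes was called, nor was any adjusted over the list alone (median 0.37, but 0.76 without Sham 1, 0.09 without Sham 2 and 0.12 without EDB 3, adjusted p = 0.0313, lost at adjusted p = 0.673 with an estimated correlation). Rrm2 had 0.81 ± 0.32, and the list was not called without Sham 2 (adjusted p = 0.651) or EDB 3 (adjusted p = 0.249), nor with scaling by library size alone (adjusted p = 0.0603). Other lists were lower in EDB than in Sham. Among 14 immediate early genes, 10 fell and 4 were not called, with 12 fallen adjusted over the list alone (median -2.07, adjusted p = 9.71e-17, held at adjusted p = 0.0247 with an estimated correlation). The neuron and synapse list had 24 tested genes, of which 4 fell and 20 were not called, with 6 fallen adjusted over the list alone (median -0.25, but -0.13 without Sham 2, adjusted p = 0.000638, lost at adjusted p = 0.233 with an estimated correlation). Shank3 fell by 1.12 ± 0.14 and Dlg4 by 0.75 ± 0.15. Of 24 tested striatal projection neuron genes, 2 fell and 22 were not called, with 1 risen and 3 fallen adjusted over the list alone (median -0.31, but -0.11 without Sham 2, adjusted p = 0.00316, lost at adjusted p = 0.541 with an estimated correlation). They were the phosphatase Ptpn5 (-0.68 ± 0.17) and Rasd2 (-0.64 ± 0.17). Ptpn5 lost its call without Sham 1, Sham 2, Sham 3, ICH 2, EDB 1, EDB 2 or EDB 3 (adjusted p from 0.0540 to 0.146) and Rasd2 without Sham 2, Sham 3, ICH 2, ICH 3, EDB 1, EDB 2 or EDB 3 (adjusted p from 0.0510 to 0.135), and the list was not called without Sham 2 (adjusted p = 0.457). Among 14 endothelial and barrier genes, 2 fell and 12 were not called, with 5 fallen adjusted over the list alone (median -0.46, adjusted p = 0.000369, lost at adjusted p = 0.228 with an estimated correlation). Lsr (-0.92 ± 0.16) and Flt1 (-0.73 ± 0.18) were those, and Flt1 lost its call without Sham 3, ICH 2, ICH 3, EDB 1, EDB 2 or EDB 3 (adjusted p from 0.0514 to 0.127), with a log2 fold change of -0.45 without Sham 3. The pericyte and smooth muscle list had 12 tested genes, of which 4 fell and 8 were not called, with 1 risen and 6 fallen adjusted over the list alone (median -0.67, adjusted p = 0.000383, lost at adjusted p = 0.233 with an estimated correlation). Vtn fell by 0.79 ± 0.14.

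The other lists were not called by camera, while fry called 2 of them upward, apoptosis (adjusted p = 0.0294) and heat shock (adjusted p = 0.0367). It did not call striatal projection neuron (adjusted p = 0.239) and cell cycle (adjusted p = 0.314), which camera called. Ependymal and choroid plexus genes had a median of 3.46 (adjusted p = 0.137) and were called upward without EDB 1 (adjusted p = 0.00567) or EDB 2 (adjusted p = 0.000309), but their median was 0.02 without EDB 3, with Ttr and Kl high in EDB 3 alone. Apoptosis genes had a median of 0.09 (adjusted p = 0.1199), with the cell cycle inhibitor Cdkn1a (1.49 ± 0.20) and Bid (1.22 ± 0.22) risen and Casp9 fallen (-0.73 ± 0.14). Heat shock genes had a median of 0.18 (adjusted p = 0.0853), with Sdf2l1 (1.05 ± 0.19) and Hspb1 (1.24 ± 0.28) risen, and were called without Sham 2 (adjusted p = 0.0372) or EDB 2 (adjusted p = 0.0311). Hspb1 lost its call without Sham 1, Sham 3, EDB 1 or EDB 3 (adjusted p from 0.0615 to 0.0811). Striatal interneuron genes had a median of -0.25 (adjusted p = 0.106) and were called downward without Sham 1 (adjusted p = 0.0213) or EDB 1 (adjusted p = 0.0206). Cholesterol genes had a median of -0.19 (adjusted p = 0.106) and were called downward without Sham 3 (adjusted p = 0.0320) or EDB 3 (adjusted p = 0.00720). GABA-A receptor genes had a median of -0.25 (adjusted p = 0.137) and were called downward without EDB 2 (adjusted p = 0.0320). Respiratory chain genes had a median of 0.11 (adjusted p = 0.411) and were called upward without Sham 2 (adjusted p = 0.0497).

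Astrocyte baseline genes had a median of -0.15 (adjusted p = 0.143), erythroid genes a median of 0.68 (adjusted p = 0.411), fibroblast genes a median of 0.50 (adjusted p = 0.314), ferroptosis genes a median of 0.16 (adjusted p = 0.374) and cortical neuron genes a median of -0.56 (adjusted p = 0.333). Thalamic genes had a median of -0.07 and a mean of -0.03 with the test pointing up (adjusted p = 0.955). Hypoxia genes had a median of -0.04, a mean of 0.02 and a test pointing up (adjusted p = 0.648). Cd8a rose by 4.37 ± 0.90 from the 3, 1 and 0 counts of the Sham libraries, a ratio of 22.2 with a 95% counting interval of 8.404 to 83.2. That call was lost without Sham 3 or EDB 1 (adjusted p from 0.0546 to 0.0636). Lck, Cd5 and Cd3e had 0.41 ± 0.36, 0.10 ± 1.02 and 0.04 ± 0.66.

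By the quasi-likelihood test 1094 of 14274 genes were called, 707 higher in EDB and 387 lower, of which 528 changed more than 2-fold. At an unadjusted p under 0.05 there were 3266, and the libraries of the groups did not overlap in 26.1% of genes, where chance gives 10%. Leaving out Sham 1, Sham 2 or Sham 3 gave 590, 1661 and 577 genes, and leaving out EDB 1 gave 508. Without Sham 2 and ICH 1 together 1978 genes were called. The share of rises ran from 48.8% with Sham 2 as the only Sham library to 78.8% with an absolute log2 fold change above 1. Camera called 24 of 38 lists with the preset correlation, 19 up and 5 down, and 4 with an estimated correlation, 3 up and 1 down. In 1 or more of the fits added after the data were seen, camera did not call the neutrophil, projection neuron, iron, cell cycle and NF-kB lists (adjusted p from 0.0504 to 0.680) and called the heat shock, striatal interneuron, apoptosis, cholesterol and respiratory chain lists, and with only the 6 libraries with liver transcripts 13 of the 62 named calls were lost.

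Genes that moved in ICH were also followed across the comparisons. Of the 98 genes called between EDB and ICH, 94 had been called in the opposite direction between ICH and Sham, and 0 in the same direction. Among them 87 had risen in ICH and were lower in EDB, Nes, Gpnmb, Lgals3, Cd44 and Rrm2 included, and 7 had fallen in ICH and were higher in EDB. Independent lists of these sizes would share 10.3 and 0.584 genes. Both comparisons use the same ICH libraries, so part of the excess may come from the shared controls. The covariance of the log2 fold changes across genes was -0.262 (r = -0.61), against -0.0590 (r = -0.497) on average in 50 simulations without any difference between groups. The count of reversed genes was 41, 231 and 36 without Sham 1, Sham 2 and Sham 3, 23, 8 and 32 without ICH 1, ICH 2 and ICH 3, and 43, 9 and 10 without EDB 1, EDB 2 and EDB 3. Between ICH against Sham and EDB against Sham, 957 genes were called in the same direction, 635 up and 322 down, where independent lists would share 80.6 and 28.3, and 0 in opposite directions. Here the Sham libraries are shared, with a covariance of 0.419 (r = 0.78) against 0.0596 (r = 0.501) in the simulations. Genes are not independent replicates, and these correlations are across genes.

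**Figure D3:**
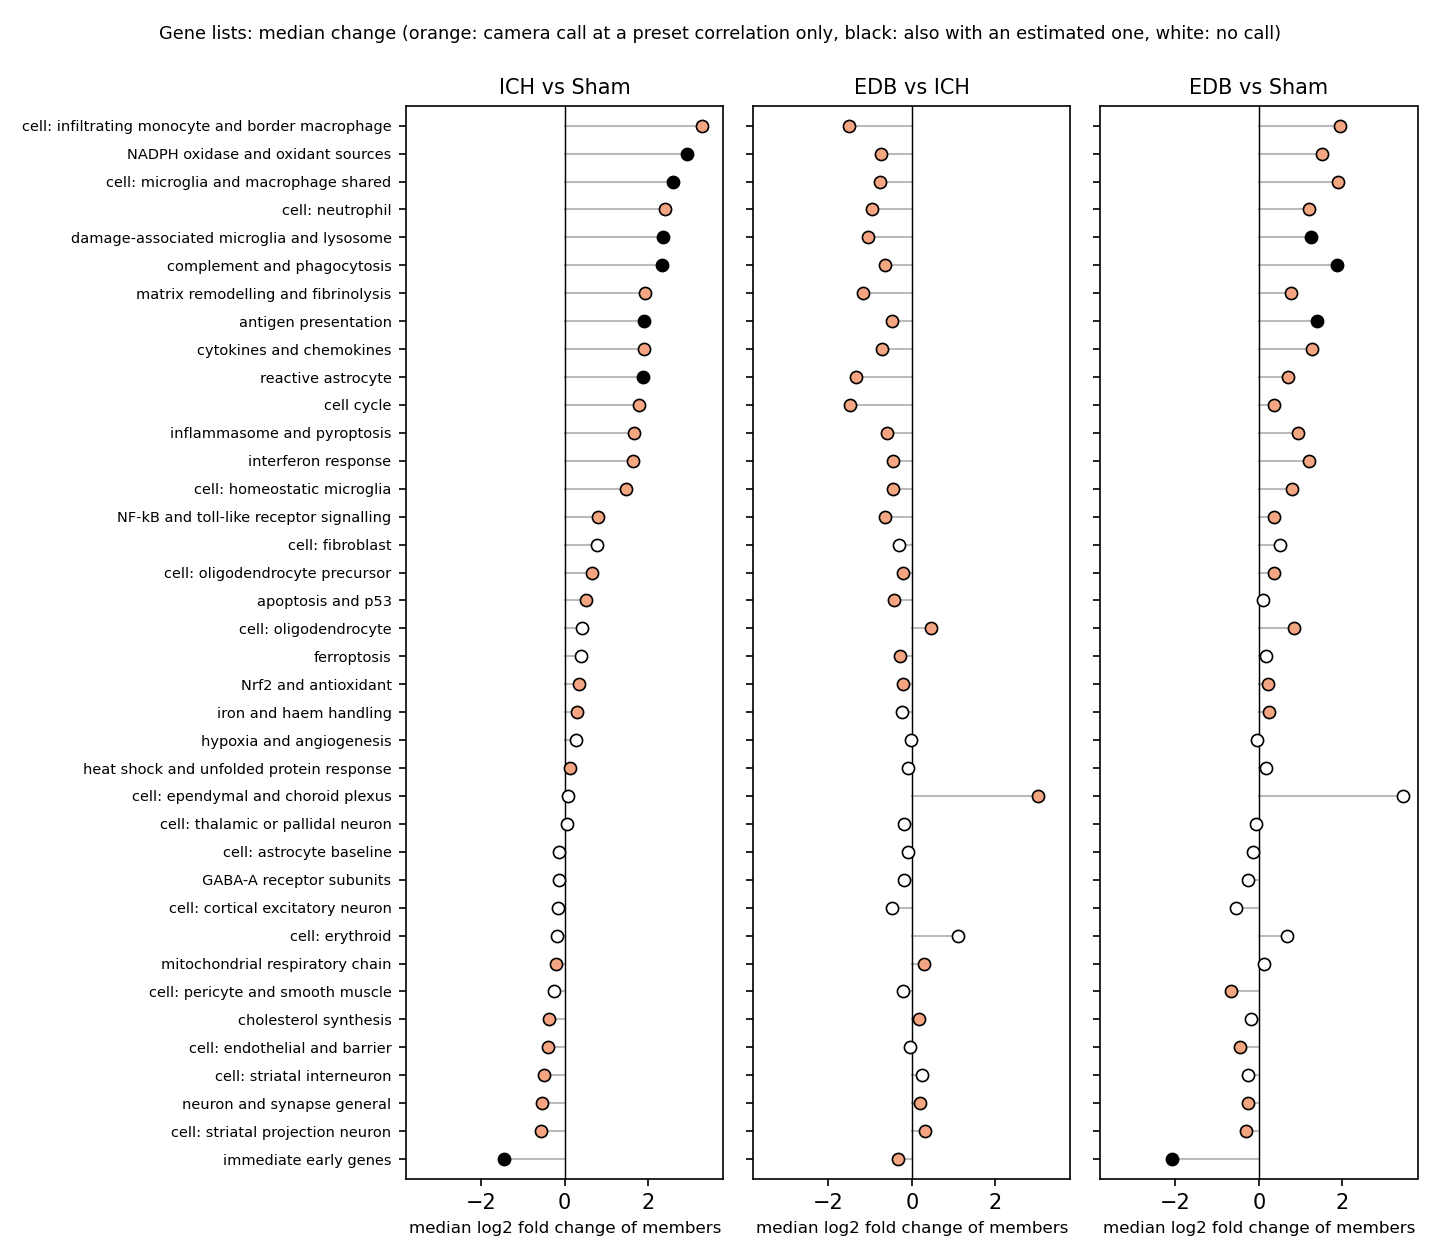
Median log2 fold change of the tested genes of each of the 38 lists in the 3 comparisons. Black points were called by camera with the preset and with an estimated correlation, orange points with the preset correlation only, and white points were not called. Microglia, complement and reactive astrocyte lists lie above 0 in ICH against Sham and in EDB against Sham, and below 0 in EDB against ICH.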

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

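Of 5167 recomputed values of the 236 gene changes named, 4482 kept their side of the threshold, 663 lost the call and 22 gained one. No gene call reversed. Some uncalled genes changed sign. Of 1710 list values, 1519 kept their side, 151 lost the call, 39 gained one and 1 reversed. The last was the choroid plexus list in EDB against ICH without EDB 3. Its median was 0.067, where the other fits without 1 library gave up to 3.58. Its test pointed down (adjusted p = 0.322). Ttr and Kl were high in EDB 3 alone. Alternatives added after the data were seen were only the 6 libraries with liver transcripts, the liver class as a batch term, the fits without Sham 1 and Sham 3 or without Sham 2 and ICH 1, and leaving out libraries of the group not compared.

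Between ICH and Sham the count of 2670 genes was 1189 with an absolute log2 fold change above 1, and 1769 to 2522 without single libraries of these groups or 2397, 2624 and 2529 without EDB 1, EDB 2 and EDB 3. Between EDB and ICH the count of 98 was 679 with DESeq2 and 187 with limma-voom, 31 with only the 6 libraries with liver transcripts, 152 with the batch term, 39 without Sham 2 and ICH 1, and 8 to 44 without single libraries of these groups. It was 41, 321 and 37 without Sham 1, Sham 2 and Sham 3. Between EDB and Sham the count of 1094 was 1767 with DESeq2, 528 with the fold change limit, 201 without Sham 1 and Sham 3, which leaves Sham 2 alone, 1978 without Sham 2 and ICH 1, and 508 to 1661 without single libraries of these groups. It was 1085, 817 and 976 without ICH 1, ICH 2 and ICH 3. The 94 genes reversed from ICH to EDB were 540 with DESeq2 and 8 to 231 without single libraries. Fits without libraries have fewer samples, and a single Sham library is assumed to vary like the other groups. The cause of the other changes was not tested.

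With the replicate number as a block, the EDB and ICH comparison called 58 genes and the reversed genes were 58, with fewer residual degrees of freedom. The numbers do not pair the libraries. After removal of group means, 2 of 9 same-number pairs correlated above 0.1, and 2 of 9 libraries were closest to their own number. Other pairs had a median of -0.02 and reached 0.33 (Sham 2 and EDB 1), and such links were not modelled. Of 38 lists, an estimated correlation called 7 in ICH against Sham, 0 in EDB against ICH and 4 in EDB against Sham, where camera with its preset called 27, 26 and 24. Fry called 11 in EDB against ICH, and it asks another question. Without single libraries of the groups compared 25 to 29, 20 to 27 and 23 to 27 lists were called. At these depths genes near 0.175 CPM in every group, the level of 3 counts in ICH 1, could not be followed. Changes under 2-fold were called in few simulated cases.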

Other observations

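All tests in this part were chosen only after the results were seen. The rise of genes in ICH was followed into EDB as the median over genes of the share of the ICH rise in CPM that EDB kept, with a jackknife SE over the libraries. Over the 1628 genes that rose in ICH, EDB kept 47.1 ± 6.72% of the rise. Homeostatic microglia genes such as Csf1r and Cx3cr1 kept 62.8 ± 18.8%, antigen presentation genes 58.0 ± 8.90%, interferon response genes 57.4 ± 12.4% and complement genes 55.4 ± 10.8%. Genes of damage-associated microglia, such as Gpnmb and Spp1, kept 30.2 ± 7.34%, reactive astrocyte genes 27.1 ± 9.12%, monocyte genes 24.1 ± 9.80% and matrix genes 18.7 ± 8.18%. Cell cycle genes kept 11.96 ± 12.8%. Single libraries moved some of these shares, to 17.96% for reactive astrocytes and 14.4% for monocytes without EDB 1, and for the cell cycle to 22.3%, 5.24%, 18.5% and 6.03% without Sham 1, Sham 2, EDB 2 and EDB 3. These lists were ordered after their values were seen, and all shares use the same 9 libraries. Choosing genes by the rise that divides the share can bias it low, which the SE omits.

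EDB lay between Sham and ICH in the median of the risen genes. One smaller share of injured tissue in the EDB samples would leave the same part of every rise. The complement list kept 43.5 percentage points more than the cell cycle list (SE 20.9), a gap of 2.08 SE that did not pass the 95% t interval with 6 degrees of freedom, and the lists were picked after their values were seen, the cell cycle list as the lowest. More white matter in the EDB samples would dilute striatal neuron genes, whose median log2 fold change from ICH to EDB was 0.298 (SE 0.123), above 0 by 2.42 SE, again inside that interval. A limit of 2 SE was set first and replaced after the values were seen, and it would have excluded both. These explanations and an effect of the drug, itself untested, cannot be told apart at this spread, and each may hold.

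ICH 1 had no Y-linked counts. At the level of ICH 2 and ICH 3, Kdm5d, Eif2s3y and Uty would have given 444 counts (lower bound 404) against 0 observed, which argues against low depth. Without ICH 1, 95.3% of the 1769 genes called against Sham placed it nearer to ICH 2 and ICH 3, which argues against a Sham library under its label, and so did 79.2% of the 24 called against EDB (lower bound 57.8%, taking genes as independent), which argues less firmly against an EDB library. The X-linked partner genes were highest in ICH 1 in 4 of 4 cases, with Eif2s3x at 143 CPM against at most 81.3 elsewhere, Kdm6a at 18.8 against 12.7, Ddx3x at 112 against 90.3 and Kdm5c, by a narrow margin, at 102 against 96.8, so a female animal is a candidate explanation. A swap with an outside sample stays open, and Xist was not analysed here.

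Cd8a rose in ICH with few T cell Cd3 counts. It had 617, 222 and 140 counts in ICH 1, ICH 2 and ICH 3, where Cd3d, Cd3e and Cd3g together had 7, 14 and 23. The latter reached 1.13% to 16.4% of Cd8a, against 0.486% to 2.25% for Nkg7, Prf1 and Klrd1 of natural killer cells, in each library beyond counting error, which argues against both as the main source. Cd8b stood at 9.80, 4.03 and 2.05 CPM in the same libraries. Macrophages could be the source, which was not tested.

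Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05, and 1 of 10 gave as many genes in each. The real splits called 2670 genes in ICH against Sham, 98 in EDB against ICH and 1094 in EDB against Sham, and the highest other splits 0, 1 and 0.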
